A study of Mus musculus with 20 samples.

How the data were processed

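The series holds 19 bulk RNA-seq libraries and 1 droplet single-cell library of mouse early T-cell progenitors. The labels give the gates as lineage-negative, 7AAD-negative, CD44+ and Kit+ cells, without CD25 (DN1, called early T-cell precursors in thymus) or with it (DN2a), the latter split by a Bcl11b fluorescent reporter. Single cells came from mice without the reporter. Bulk RNA was extracted with a micro column kit, made into libraries with a NEBNext Ultra kit and read as single reads, per the labels' protocols, which do not state a strand-marking step. The single-cell library used 10x Chromium 3' version 2 chemistry, per the labels' protocols.

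The bulk table holds RPKM values, reads per kilobase of exon scaled to the mapped reads of the library, which the authors deposited for 24506 genes. Per the file headers they came from HOMER, counting exons of mm10 RefSeq models and merging transcripts of a gene. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.0, RSEM 1.2.25, HOMER, edgeR 3.6.8 and Cell Ranger 2.0 and the build GRCm38 (mm10), with no order or role. Columns were matched to samples by name. The pair of thymic DN1 columns could be placed in their group but not numbered, and 5 columns match no sample and were not used. The single-cell matrix holds UMI counts per gene and cell, deposited after the authors' own barcode filter, per the labels and the values, which are all whole.

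Positions are 1-based as the table gives them. Of 517 genes compared with GENCODE release M21 on the same build, 514 shared a symbol with it and 512 overlapped in position. The bulk values include 394 genes with more than 1 copy, and such genes, overlapping genes and antisense pairs were read as uncertain.

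RPKM values carry no read totals, so depth was recovered from them. With the gene length given, low values came out as whole multiples of 1 read: 100% of the values tested per library, within a tolerance of 0.01 reads for values up to 8 reads, against 3.0% to 5.8% by chance. This gave 13.3 M to 47.0 M mapped reads per library (M for mega). A level listed at 0 is compatible with up to 3 reads, so absence was not read from it.

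Genes with at least 1 RPKM in at least 2 libraries were tested, 12349 in all. The bulk test was limma 3.58.1 (R 4.3.3) on log2(RPKM + 1) with a trended and robust prior, and Benjamini-Hochberg adjusted p-values with a threshold of 0.05. Fold changes are on this log2(RPKM + 1) scale, which understates the change of low genes. The model had stage and system as additive terms over the 19 libraries, which share 1 estimate of spread because no group has more than 2 libraries. The contrasts were DN2a Bcl11b- against DN1, DN2a Bcl11b+ against DN2a Bcl11b-, the 3 cultures against thymus together and singly, ATO-DLL4 against ATO-DLL1 and ATO-DLL4 against OP9-DLL4. Late against early day was fitted with the group as a block over 12 culture libraries, and the difference of stage effects with a mean per group. Values of RPKM in the text are means over the libraries of an arm, while fold changes come from the model, so the 2 can differ where stages are unequally filled.

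The 21 gene lists were T-lineage, Notch targets, progenitor regulators, myeloid, mast and basophil, erythroid and megakaryocyte, B-cell, dendritic-cell, innate lymphoid and NK, DN3 and later T, stromal, cell cycle, interferon response, immediate early and stress, glycolysis and hypoxia, cholesterol synthesis, amino acid response, homing and adhesion, cytokine feedback, ribosomal and translation, and sex-linked genes. The stage markers in them are textbook knowledge and some genes stand in 2 lists (Il2ra in the T-lineage and Notch lists). Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Of 86 list calls with the preset value, 13 held with the estimated one. For every named list the members past the threshold were also counted adjusted over the list alone.

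Named genes followed a fixed rule: the gate and reporter genes Il2ra, Bcl11b, Kit and Cd44, the 6 largest rises and 6 largest falls among genes that passed with at least 10 RPKM in the higher arm, and up to 2 members per list and direction. Some further genes, such as Fn1 and Myc between the organoids, were named after the data were seen. The groups, tests, covariates, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were a pseudocount of 0.1, no filter, quantile normalization, a mean per group and a block for system and day. Others were each system alone, only the systems compared, and each library left out in turn. For each system alone, the contrast was taken within that system in a fit with a mean per group over all 19 libraries. Its spread therefore also came from libraries of the other systems. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood) on the recovered whole reads, leaving out the OP9-DLL4 libraries, both OP9-DLL4 DN1 libraries or 2 stroma-carrying ATO-DLL4 libraries, the contrast of stage effects between OP9-DLL4 and the organoids, and the contrast of OP9-DLL4 DN1 with organoid DN1.

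On simulated RPKM with 200 changed genes among 12349, limma found 11.9% to 82.1% of genes changed 1.5-fold, 58.2% to 95.5% changed 2-fold and 92.4% to 100% changed 4-fold over the 11 contrasts, with at most 15 unchanged genes called. The noise there was drawn from the spread that limma itself had fitted. On simulated counts edgeR called 57 unchanged genes for cultures against thymus. It called 401 for the difference of stage effects between cultures and thymus and 466 for that between OP9-DLL4 and organoids.

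Single cells were handled with scanpy 1.11.5 (Python 3.11.15). Cells with at least 1000 genes and under 10% mitochondrial UMIs were kept. Counts were log-normalized, reduced to 2000 variable genes and 30 principal components, and clustered with leidenalg 0.10.2 at resolution 1 with 15 neighbours. A cluster was named from fixed markers only when at least 3 of a class were among its 10 leading genes by fold. Scrublet marked 13 of 6239 cells (0.21%). This was taken as too few to act on, and whether Scrublet worked was not tested. No doublets were removed, so mixed droplets remain possible. Cells were thinned to 5000 UMIs to compare shares. No test was made on cells.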

Results

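The earliest stages of T-cell development were profiled in mouse progenitors taken from the thymus or grown in 3 culture systems. Bulk RNA sequencing covered the thymus and the 3 cultures, and 1 culture was also profiled by droplet single-cell RNA sequencing. Bulk samples came from C57BL/6 mice carrying a fluorescent reporter of Bcl11b, a transcription factor that marks commitment to the T lineage. Cells were sorted into 3 stages. DN1 cells carried CD44 and Kit without CD25, the gate that holds early T-cell precursors in the thymus. DN2a cells had gained CD25, the protein made from Il2ra, and were split into reporter-negative (DN2a Bcl11b-) and reporter-positive (DN2a Bcl11b+) cells.

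The cultures began with bone marrow cells depleted of mature lineages. OP9-DLL4 is a layer of OP9 stromal cells that display the Notch ligand DLL4. The artificial thymic organoids (ATO) are aggregates with MS5 stromal cells displaying DLL1 or DLL4, called ATO-DLL1 and ATO-DLL4 here. The 19 bulk libraries fell into 12 groups, with 4 libraries from thymus and 5 from each culture. Each culture gave 2 DN1, 2 DN2a Bcl11b- and 1 DN2a Bcl11b+ library, and the thymus gave 2, 1 and 1. The 2 libraries of a DN1 or DN2a Bcl11b- culture stage were taken on days 4 and 6 in OP9-DLL4 and on days 5 and 6 in the organoids. The DN2a Bcl11b+ library was of day 6 in OP9-DLL4 and was labelled days 5-6 in each organoid. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, part of which may be technical. In the additive model this spread also holds differences between sampling days and stage effects that differ between systems.

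Depth ranged from 13.3 M mapped reads (M for mega) in the first OP9-DLL4 DN2a Bcl11b- library to 47.0 M reads in the second OP9-DLL4 DN1 library. In the 7 groups that had a pair of libraries, the chi-square per degree of freedom between them was 8.08 to 40.8 against read-counting error only, and each library was counted on its own. The first principal component held 26.6% of the variance and the second 24.5%. The OP9-DLL4 columns were matched to samples by name, in a table with 5 further columns that match no sample here, and values for that system rest on this match.

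**Figure D1:**
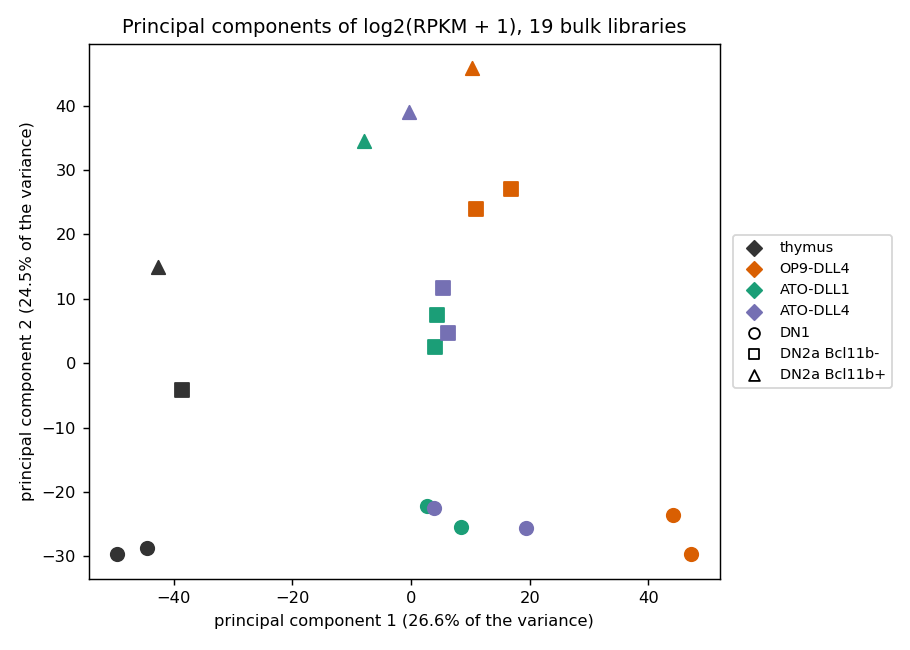
Principal components of log2(RPKM + 1) for the 19 bulk libraries, coloured by system and shaped by stage. The horizontal axis (26.6% of the variance) runs from the thymic libraries to the OP9-DLL4 DN1 libraries, and the vertical axis (24.5%) orders DN1, DN2a Bcl11b- and DN2a Bcl11b+ within each system.

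The first comparison asked what changed when cells gained CD25 before they switched on the Bcl11b reporter. The myeloid and progenitor lists were lower in the sorted DN2a Bcl11b- population (both adjusted p = 0.0284 with an estimated correlation) and the T-lineage list was higher (adjusted p = 0.137 with an estimated correlation). Il2ra, which encodes the sorted marker CD25 and so checks the gate, averaged 306 RPKM in 7 DN2a Bcl11b- libraries and 3.77 RPKM in 8 DN1 libraries. It rose by 6.38 ± 0.33 (log2, SE; limma adjusted p = 5.47e-09). Tcf7, a transcription factor that starts T-cell specification, rose by 2.52 ± 0.34 to 283 RPKM, and Fgf3, a growth factor gene, rose by 4.53 ± 0.23. Flt3, a cytokine receptor of multipotent progenitors, fell by 3.82 ± 0.16, and Elane, which encodes neutrophil elastase, fell by 4.66 ± 0.24, from 112 to 3.70 RPKM. Il2ra lies at positions 11642792 to 11693194 of chromosome 2 on the plus strand (mm10).

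Of 34 measured T-lineage genes, 21 rose and 1, Gfi1, fell (camera adjusted p = 1.26e-13), although adjusted p = 0.137 with an estimated correlation. Adjusted over the list alone, 24 passed. Il7r, the receptor for a survival cytokine of lymphocytes, rose by 1.45 ± 0.13. Among 15 Notch targets, 6 rose, the sorted marker Il2ra among them, and 1 fell (camera adjusted p = 7.68e-04), and adjusted p = 0.0729 with an estimated correlation. Dtx1, a target of Notch signalling, rose by 1.27 ± 0.30 to 13.9 RPKM. Adjusted over the list alone, 10 Notch targets passed. Of 14 DN3 and later T genes, 5 rose, among them Rag1, a recombinase of receptor gene rearrangement, by 1.11 ± 0.25 (camera adjusted p = 0.0121, and adjusted p = 0.528 with an estimated correlation).

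Myeloid genes were the list with most members falling: 20 of 28 fell and 1 rose (camera adjusted p = 1.51e-18, and adjusted p = 0.0284 with an estimated correlation). Prtn3, a neutrophil granule protease, fell by 3.01 ± 0.40, and S100a8, an abundant neutrophil and monocyte protein, fell by 3.34 ± 0.32. The single riser was Fcer1g, an adaptor of Fc receptors that other blood cells also use, at 0.83 ± 0.14. Progenitor regulators fell for 14 of 24 and rose for 5 (camera adjusted p = 1.81e-06, and adjusted p = 0.0284 with an estimated correlation). Lmo2, a regulator of blood stem cells, fell by 2.44 ± 0.19, while Mycn, a growth-promoting transcription factor, rose by 1.13 ± 0.26. Adjusted over the list alone, 23 myeloid genes and 20 progenitor regulators passed. Kit, the stem cell factor receptor used in the gate, rose by 0.84 ± 0.17, and Cd44, also used in the gate, fell by 0.88 ± 0.10.

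Cytokine feedback genes rose for 10 of 19 and fell for 3 (camera adjusted p = 8.40e-05, and adjusted p = 0.0170 with an estimated correlation). Socs2, an inhibitor of cytokine signalling, rose by 1.56 ± 0.22, and Bcl6, a transcriptional repressor, fell by 0.95 ± 0.14. Cholesterol synthesis genes rose for 9 of 25 (camera adjusted p = 1.81e-06, and adjusted p = 0.0729 with an estimated correlation). Among mast and basophil genes 1 rose and 6 of 13 fell (camera adjusted p = 0.0096, and adjusted p = 0.355 with an estimated correlation). The riser was Cpa3, a mast cell carboxypeptidase also made in progenitors, at 1.94 ± 0.35, and Hdc, the enzyme that makes histamine, fell by 2.38 ± 0.35. In the erythroid and megakaryocyte list 3 of 7 rose and 4 fell, the median being -0.58 and the mean 0.60 (camera adjusted p = 0.641). The adult beta-globin genes Hbb-bs and Hbb-bt rose by 2.70 ± 0.24 and 2.69 ± 0.24, and since they are near-identical their separate values are uncertain. The same holds for the neighbouring Khdc1a and Khdc1c, at 3.17 ± 0.34 and 3.24 ± 0.38. Among innate lymphoid and NK genes 5 of 21 rose and 2 fell (camera adjusted p = 0.0216, and adjusted p = 0.790 with an estimated correlation). The median of this list was 1.92 within OP9-DLL4, -0.19 within thymus, 0 within each organoid and -0.13 without the OP9-DLL4 libraries. Gzma, a cytotoxic granule protease, rose by 4.85 ± 0.75.

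In all, 1873 of 12349 genes tested passed in limma, 813 higher and 1060 lower in DN2a Bcl11b- cells, against 1012 without the filter on low values and 2999 with a mean per group. The OP9-DLL4 DN1 libraries carried B-cell transcripts that were low in the other DN1 libraries, such as Cd79a, a signalling chain of the B-cell receptor, at 13.7 and 18.3 RPKM against at most 0.367 RPKM. The B-cell list had 1 of 13 members falling (camera adjusted p = 0.00472, and adjusted p = 0.725 with an estimated correlation), and the sign of its median turned without the OP9-DLL4 libraries, at 0.04. Within thymus alone, where 2 DN1 libraries face 1 DN2a library, 1377 genes passed, 968 higher and 409 lower, while Tcf7, Kit, Gzma, Socs2 and Bcl6 did not, and Rag1 stood at -0.002. Within OP9-DLL4 alone 3418 genes passed, within ATO-DLL1 627 and within ATO-DLL4 1001, and Dtx1 passed neither within thymus nor within either organoid. All these contrasts within 1 system, the thymic one included, took their spread from all 19 libraries.

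**Figure D2:**
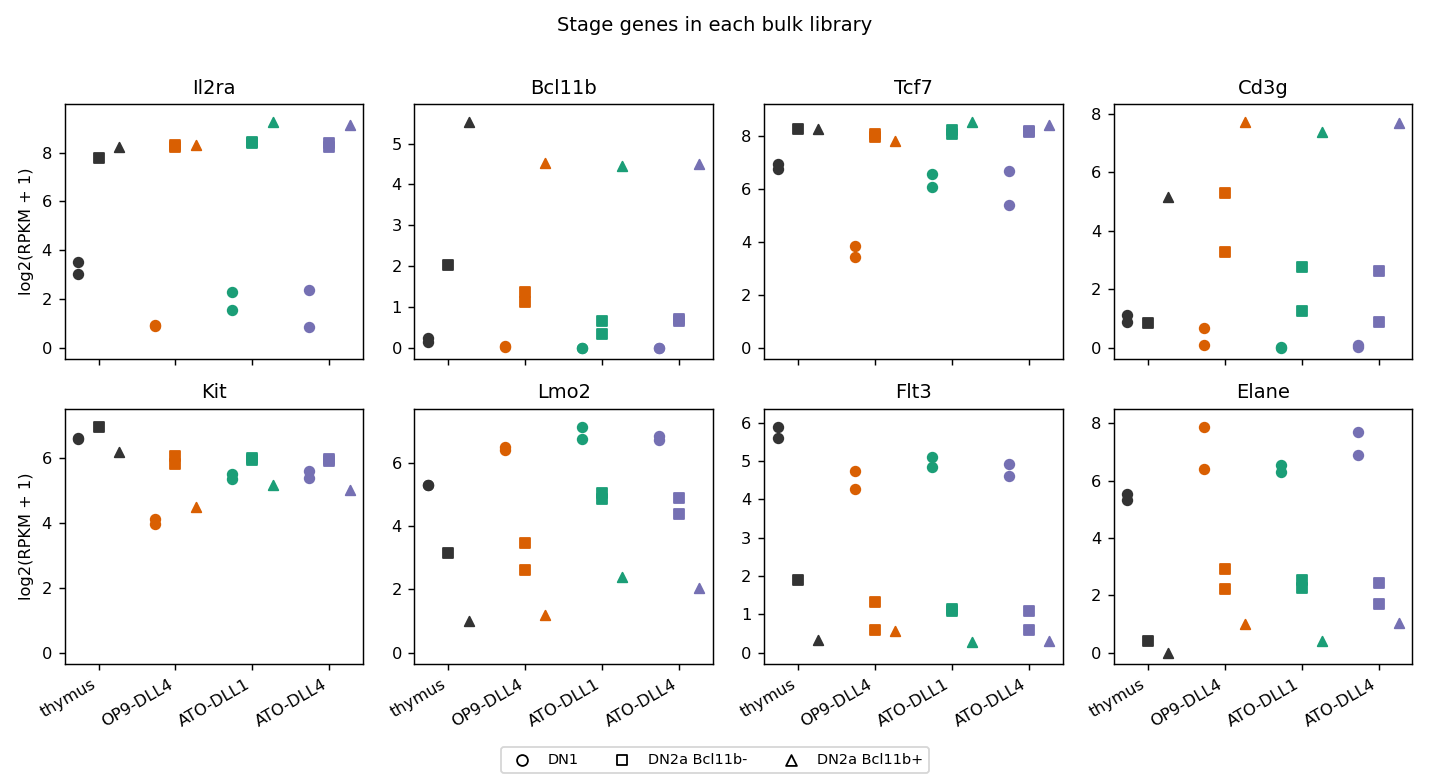
Level of 8 stage genes, as log2(RPKM + 1), in each of the 19 bulk libraries (1 point per library, colour for the system, shape for the stage). Il2ra was at most 10.6 RPKM in every DN1 library and at least 221 RPKM in every DN2a library, and Bcl11b was between 21.1 and 44.8 RPKM in the 4 reporter-positive libraries.

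The second comparison set reporter-positive against reporter-negative DN2a cells, which both carry CD25. Bcl11b itself, at positions 107910403 to 108003414 of chromosome 12 on the minus strand, averaged 27.4 RPKM in 4 reporter-positive libraries and 1.12 RPKM in 7 reporter-negative libraries, a rise of 3.70 ± 0.18 (limma adjusted p = 3.50e-09) that checks the sort. Cd3g, a chain of the T-cell receptor complex, rose by 4.63 ± 0.62 to 152 RPKM (limma adjusted p = 2.57e-04) and Cd3e by 3.59 ± 0.60 to 49.9 RPKM. Cd34, a surface protein of stem and progenitor cells, fell by 2.33 ± 0.17, and Mpo, the neutrophil myeloperoxidase, fell by 3.24 ± 0.42. Il2ra differed by 0.41 ± 0.40 and did not pass (limma adjusted p = 0.611).

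Of 34 T-lineage genes 19 rose and 0 fell (camera adjusted p = 4.39e-20, and adjusted p = 0.0982 with an estimated correlation), with 25 passing when adjusted over the list alone. Themis, a signalling protein of developing T cells, rose by 2.57 ± 0.29. DN3 and later T genes rose for 6 of 14 (camera adjusted p = 7.68e-08, and adjusted p = 0.0982 with an estimated correlation), among them Rag1, from 2.41 to 13.8 RPKM, and the receptor gene Notch3, from 3.77 to 8.75 RPKM. Progenitor regulators fell for 14 of 24 and rose for 0 (camera adjusted p = 4.60e-13, and adjusted p = 0.00237 with an estimated correlation). Lmo2 fell by 2.29 ± 0.23, to 2.39 RPKM, and Kit fell by 1.02 ± 0.20. Myeloid genes fell for 12 of 28 (camera adjusted p = 2.08e-08, and adjusted p = 0.148 with an estimated correlation), including Tyrobp, an adaptor of myeloid and NK receptors, which fell by 2.39 ± 0.27.

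Cytokine feedback genes rose for 4 of 19 and fell for 1 (camera adjusted p = 1.46e-04, and adjusted p = 0.0117 with an estimated correlation). Socs1 and Socs2, inhibitors of cytokine signalling, rose by 1.29 ± 0.27 and 1.59 ± 0.26. Cell cycle genes rose for 8 of 34 (camera adjusted p = 4.36e-09, and adjusted p = 0.305 with an estimated correlation), with Ube2c, a ubiquitin enzyme of mitosis, at 0.71 ± 0.12. In the erythroid and megakaryocyte list 4 of 7 fell and 1 rose (camera adjusted p = 0.0093, and adjusted p = 0.133 with an estimated correlation), and Itga2b, a platelet integrin also made in progenitors, fell by 1.95 ± 0.29. Notch targets rose for 3 of 15 and fell for 1, Myc, a growth regulator, which fell by 0.46 ± 0.10 (camera adjusted p = 0.0505). Ribosomal and translation genes fell for 3 of 32 (camera adjusted p = 0.00676, and adjusted p = 0.573 with an estimated correlation). Ctla4, a T-cell inhibitory receptor, rose by 2.99 ± 0.62, and H19, an imprinted noncoding RNA, rose by 2.79 ± 0.40.

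In limma 1130 genes passed, 555 higher and 575 lower. A block for system and day left 123 (56 higher, 67 lower), in a fit where each organoid Bcl11b+ library stands alone in its block. The reporter-positive arm has 1 library per system, so leaving out the library of OP9-DLL4, ATO-DLL1 or ATO-DLL4 left 703, 662 or 697 genes. Without the filter on low values 430 genes passed (257 higher, 173 lower) and with a mean per group 2314. Within thymus, where 1 library faces 1, Cd3g and Cd3e differed by 4.30 and 2.70. Within OP9-DLL4, with 1 reporter-positive library, they differed by 3.41 and 2.77. A single library in an arm has no spread of its own, so no calls are given here for these contrasts.

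**Figure D3:**
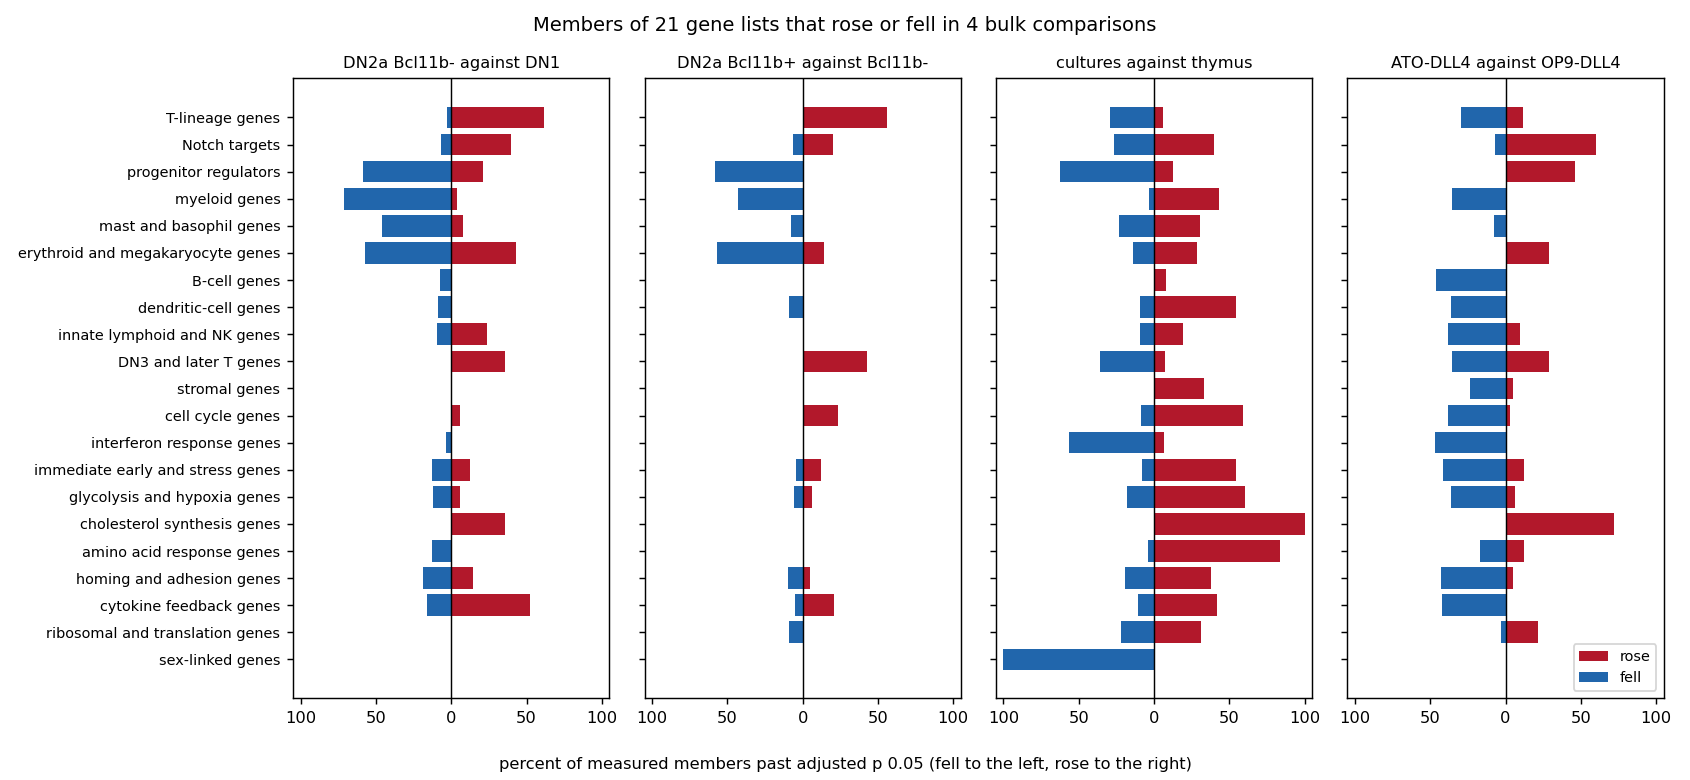
Percent of the measured members of each of 21 gene lists that rose (red, right) or fell (blue, left) at a limma adjusted p under 0.05 in 4 bulk comparisons. All 25 measured cholesterol synthesis genes rose in the cultures against thymus, and 20 of 28 myeloid genes fell from DN1 to DN2a Bcl11b-.

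The third comparison set the 3 cultures, weighted equally, against the thymus at matched stages, and asked how closely cells grown outside the body match those inside it. The cholesterol synthesis and amino acid response lists were higher in culture (adjusted p = 0.00338 and 0.314 with an estimated correlation). Mt1, a metal-binding protein, rose by 4.73 ± 0.25 in culture (limma adjusted p = 3.62e-09), from 2.03 RPKM in 4 thymic libraries to 86.0 RPKM in 15 culture libraries. Dntt, the polymerase that adds bases at antigen receptor junctions, fell by 5.98 ± 0.51 (limma adjusted p = 3.55e-07), from 361 to 24.6 RPKM, and Sytl4, a vesicle trafficking gene, fell by 3.32 ± 0.13. The culture mean of Dntt rests mostly on the OP9-DLL4 DN2a Bcl11b+ library, at 302.8 RPKM, and the other 14 culture libraries had at most 16.39 RPKM. Library numbers run together within each system, so that library batch and system cannot be told apart in this and the following comparisons between systems.

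All 25 measured cholesterol synthesis genes rose in culture (camera adjusted p = 8.52e-21, and adjusted p = 0.00338 with an estimated correlation). Fdps, an enzyme of the mevalonate pathway, rose by 1.88 ± 0.14, from 38.8 to 144 RPKM, and Mvd, another enzyme of that pathway, rose by 1.94 ± 0.12. Amino acid response genes rose for 20 of 24 and fell for 1 (camera adjusted p = 1.80e-08, and adjusted p = 0.314 with an estimated correlation), led by Asns, asparagine synthetase, at 2.53 ± 0.23. Glycolysis and hypoxia genes rose for 20 of 33 and fell for 6 (camera adjusted p = 3.96e-05, and adjusted p = 0.154 with an estimated correlation), led by the glycolytic enzyme Eno1 at 1.75 ± 0.13. Immediate early and stress genes rose for 13 of 24 and fell for 2 (camera adjusted p = 4.33e-04, and adjusted p = 0.323 with an estimated correlation), with Junb, a stimulus-induced transcription factor, at 1.70 ± 0.23. Cell cycle genes rose for 20 of 34 and fell for 3 (camera adjusted p = 4.33e-04, and adjusted p = 0.646 with an estimated correlation), and Plk1, a mitotic kinase, rose from 17.6 to 36.8 RPKM.

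Interferon response genes fell for 17 of 30 and rose for 2 (camera adjusted p = 0.0301, and adjusted p = 0.752 with an estimated correlation), with Ifi44, an interferon-induced gene, falling by 1.53 ± 0.35. In OP9-DLL4 alone 5 rose and 5 fell (median -0.19; camera adjusted p = 0.996), while 17 fell in ATO-DLL1 and 18 in ATO-DLL4 (adjusted p = 0.826 and 0.769 with an estimated correlation). Myeloid genes rose for 12 of 28 and fell for 1 (camera adjusted p = 2.29e-04, and adjusted p = 0.490 with an estimated correlation), with Prtn3 at 2.66 ± 0.44. Among progenitor regulators 15 of 24 fell and 3 rose (camera adjusted p = 0.109), Kit falling by 1.36 ± 0.18 and Lmo2 rising by 1.19 ± 0.21. T-lineage genes fell for 10 of 34 and rose for 2 (camera adjusted p = 0.195), Il7r falling by 1.86 ± 0.14 and Thy1, a surface marker of T cells, rising by 1.54 ± 0.36. Among Notch targets 6 of 15 rose and 4 fell (camera adjusted p = 0.251), Notch1, the receptor, falling by 0.94 ± 0.15. Homing and adhesion genes rose for 8 of 21 and fell for 4 (camera adjusted p = 0.159), and Itga4, an integrin of cell homing, fell by 1.32 ± 0.17. Dendritic-cell genes rose for 6 of 11 and fell for 1 (camera adjusted p = 0.109), Cd74, the chaperone of class II molecules, rising by 3.22 ± 0.68. Gzmb, a cytotoxic granule protease, rose by 4.10 ± 0.74. Xist, the RNA that silences 1 X chromosome in female cells, fell by 1.41 ± 0.10, from 209 to 77.2 RPKM. The 2 measured sex-linked genes both fell (too few for camera), the other being its antisense partner Tsix, which fell by 1.47 ± 0.14, and since no strand-marking kit is stated the 2 cannot be read separately. Ribosomal and translation genes rose for 10 of 32 and fell for 7 (camera adjusted p = 0.338).

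In limma 6829 genes passed, 3007 higher and 3822 lower in culture, while edgeR gave 3500 higher and 3350 lower and quantile normalization 3102 and 3547. Stromal genes rose for 7 of 21, of which 2 passed when adjusted over the list alone (camera adjusted p = 0.0206, and adjusted p = 0.722 with an estimated correlation). The median of the list against thymus was 0.96 in OP9-DLL4, 1.05 in ATO-DLL4 and 0.08 in ATO-DLL1. Thbs1, a matrix protein, was at 10.3 to 84.1 RPKM in OP9-DLL4 and listed at 0 in the 4 thymic libraries, and Col1a1, a fibroblast collagen, reached 23.32 RPKM in OP9-DLL4 and 28.02 RPKM in ATO-DLL4. Neither Thbs1 nor Cxcl12, a stromal chemokine, passed without OP9-DLL4.

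Taken 1 culture at a time, OP9-DLL4 differed from thymus at 6915 genes (3095 higher, 3820 lower), ATO-DLL4 at 5933 (2514 and 3419) and ATO-DLL1 at 5399 (2434 and 2965) in limma. In edgeR the splits turned, to 3622 higher and 3224 lower, 3123 and 2799, and 2808 and 2495. Ccr2, a chemokine receptor of monocytes, rose by 4.61 ± 0.15 in OP9-DLL4, from 1.78 to 67.8 RPKM. In OP9-DLL4, 21 of 28 myeloid genes rose and 1 fell (camera adjusted p = 1.65e-07, and adjusted p = 0.174 with an estimated correlation), and 15 of 24 progenitor regulators fell and 0 rose (camera adjusted p = 0.00102, and adjusted p = 0.145 with an estimated correlation). Hes1, a direct Notch target, fell by 1.59 ± 0.29 in OP9-DLL4. Dntt fell by 3.49 ± 0.61 in OP9-DLL4, by 7.20 ± 0.61 in ATO-DLL1 and by 7.27 ± 0.61 in ATO-DLL4. Mt1 rose by 4.22 ± 0.30, 4.77 ± 0.30 and 5.20 ± 0.30 in the same order. Cholesterol synthesis genes rose for 24 of 25 in OP9-DLL4 (camera adjusted p = 9.14e-14, and adjusted p = 0.0200 with an estimated correlation) and for 25 of 25 in each organoid (adjusted p = 0.00143 and 0.00131 with an estimated correlation).

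**Figure D4:**
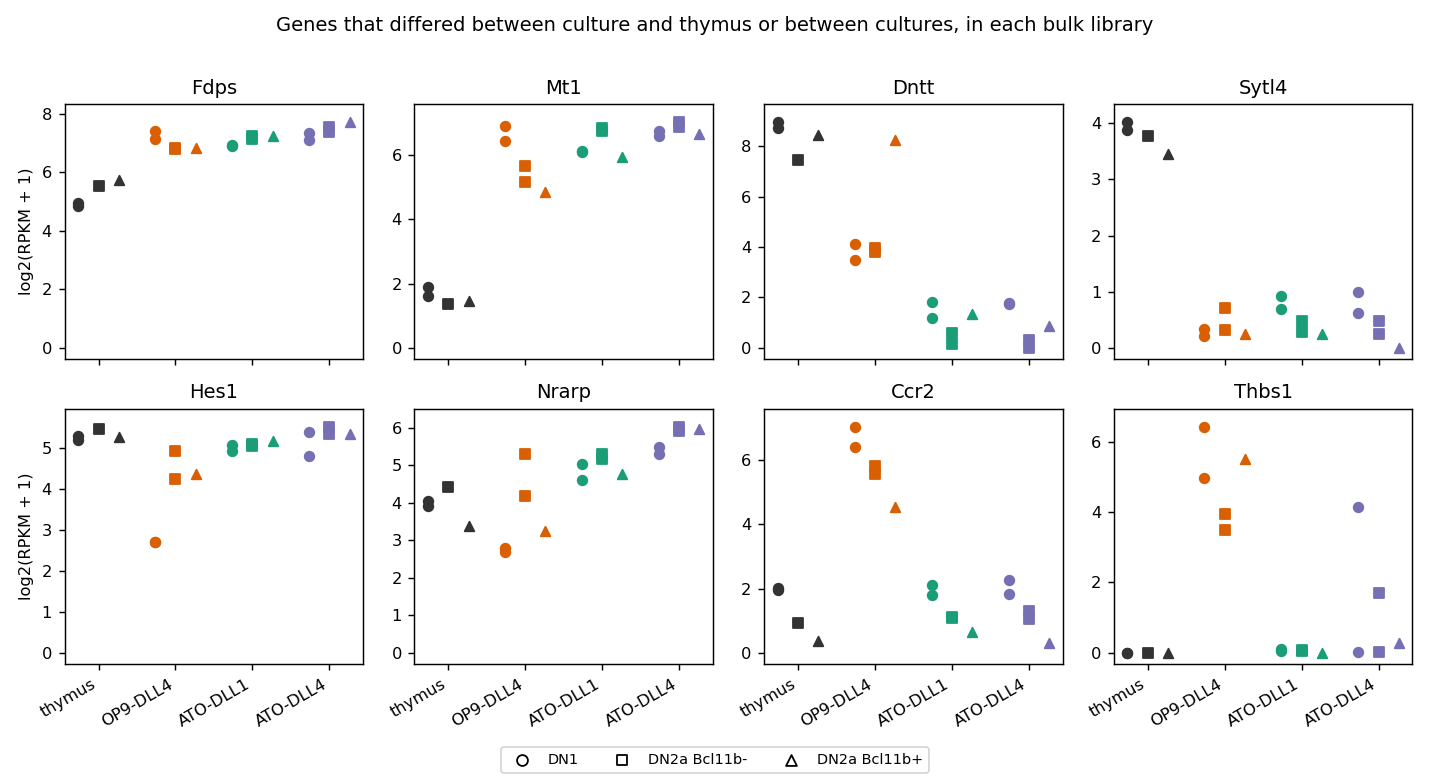
Level of 8 genes, as log2(RPKM + 1), in each of the 19 bulk libraries (1 point per library, colour for the system, shape for the stage). Mt1 and Fdps were higher in all 15 culture libraries than in the 4 thymic libraries, while Hes1 was near 5.5 RPKM in both OP9-DLL4 DN1 libraries and at least 18 RPKM in the other 17.

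The fourth comparison asked whether the Notch ligand on organoid stroma, DLL4 or DLL1, changed the cells, with stages and days matched. The ligand label of 2 ATO-DLL4 libraries is in doubt, as given below. In limma 1 of 12349 genes passed, Ppt1, a lysosomal enzyme, which fell by 0.52 ± 0.07 with DLL4 (adjusted p = 0.0199), named because the count was so small and after its value was seen. At an unadjusted p under 0.05 there were 577 genes, and edgeR called 1. Notch targets had 0 of 15 members passing and a median of 0.04. Il2ra differed by -0.17 ± 0.40, Kit by -0.01 ± 0.20 and Myc by 0.07 ± 0.10, none past the threshold (limma adjusted p = 1 for each). On data simulated for this contrast over all 19 libraries, limma found 95.5% of genes changed 2-fold and 70.1% of those changed 1.5-fold. Noise there was independent between genes, and changed genes were drawn from those above a low level. No simulated library carried stroma, so these shares do not show which changes could be found in the real organoid libraries.

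Stromal transcripts had the largest mean change of the lists between the organoids, at 0.93 and 0 of 21 passing singly (camera adjusted p = 6.07e-11, and adjusted p = 0.522 with an estimated correlation). They lay in 2 ATO-DLL4 libraries: Col1a1 was at 28.02 RPKM in the first DN1 library and 6.82 RPKM in the second DN2a Bcl11b- library, and at most 0.229 RPKM in the other 8 organoid libraries. The first of these 2 libraries held 3232 reads of Dll1 and 5837 of Dll4 and the second 1872 and 16, so the ligand label of both is in doubt. Fn1, a matrix protein, differed by 1.94 ± 0.87 and did not pass. Cholesterol synthesis genes had a median of 0.13 (camera adjusted p = 6.07e-11, and adjusted p = 0.0528 with an estimated correlation) and amino acid response genes one of 0.14 (camera adjusted p = 3.11e-05, and adjusted p = 0.595 with an estimated correlation), with 0 members of either passing singly. With only these 10 libraries in the fit 69 genes passed, and without the 2 stroma-carrying libraries, a setting chosen after seeing the data, 0 did.

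The fifth comparison set the organoid against the OP9 layer, both labelled with the ligand DLL4. The ligand label of the 2 stroma-carrying ATO-DLL4 libraries is in doubt, so the same ligand is not certain for them. Days differ in part and stroma, culture form and library batch all go with the system. The Notch target and progenitor lists were higher in the organoid, with medians of 0.73 and 0.62 (adjusted p = 0.0392 and 0.0270 with an estimated correlation). Nrarp, a feedback regulator induced by Notch, was higher in the organoid by 2.09 ± 0.28 (limma adjusted p = 1.11e-04), at 53.3 against 15.03 RPKM over 5 libraries each, and Hes1 by 1.49 ± 0.27. Ccr2 fell by 4.53 ± 0.14 in the organoid, to 1.83 RPKM.

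Of 15 Notch targets 9 rose in the organoid and 1 fell (camera adjusted p = 6.27e-05, and adjusted p = 0.0392 with an estimated correlation). Progenitor regulators rose for 11 of 24 and fell for 0 (camera adjusted p = 1.74e-06, and adjusted p = 0.0270 with an estimated correlation), among them Nfe2, a transcription factor of the megakaryocyte lineage, at 1.38 ± 0.11 and Cd34 at 1.16 ± 0.17. Cholesterol synthesis genes rose for 18 of 25 and fell for 0 (camera adjusted p = 5.77e-14, and adjusted p = 0.0189 with an estimated correlation). Cytokine feedback genes fell for 8 of 19 (camera adjusted p = 0.00388, and adjusted p = 0.0392 with an estimated correlation), Bcl2, a survival gene, falling by 1.38 ± 0.23. Myeloid genes fell for 10 of 28 (camera adjusted p = 8.26e-06, and adjusted p = 0.310 with an estimated correlation), with the macrophage lysozyme gene Lyz2 falling by 3.13 ± 0.27. Interferon response genes fell for 14 of 30 (camera adjusted p = 7.94e-07, and adjusted p = 0.348 with an estimated correlation) and B-cell genes for 6 of 13 (camera adjusted p = 6.61e-05, and adjusted p = 0.348 with an estimated correlation). Innate lymphoid and NK genes fell for 8 of 21 and rose for 2 (camera adjusted p = 7.74e-04, and adjusted p = 0.398 with an estimated correlation), with Il2rb, a cytokine receptor of NK and activated T cells, falling by 3.23 ± 0.66. T-lineage genes fell for 10 of 34 and rose for 4, with a median of -0.33 (camera adjusted p = 0.0913), Ly6d, a lymphoid surface protein, falling by 2.35 ± 0.31 and Lat, an adaptor of the T-cell receptor, rising by 1.90 ± 0.48. Adjusted over the list alone, 11 Notch targets, 13 progenitor regulators, 12 myeloid genes and 11 B-cell genes passed.

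Without both OP9-DLL4 DN1 libraries, a setting chosen after seeing the data, 8 of 15 Notch targets and 13 of 24 progenitor regulators rose, with medians of 0.68 and 0.51. Both lists passed there (camera adjusted p = 3.62e-04 and 2.22e-06), although not with an estimated correlation (adjusted p = 0.0699 and 0.0562 with an estimated correlation). In the same setting T-lineage genes fell for 17 of 34 and rose for 3, with a median of -0.75 (camera adjusted p = 1.68e-06, and adjusted p = 0.103 with an estimated correlation), and innate lymphoid and NK genes fell for 13 of 21 (camera adjusted p = 9.80e-10, and adjusted p = 0.0910 with an estimated correlation). There Hes1 was higher by 0.84 ± 0.15 and Nrarp by 1.62 ± 0.28, and both passed, while Kit, at 0.20 ± 0.11, did not (limma adjusted p = 0.211). The B-cell list lost its call there (camera adjusted p = 0.198). In that setting 17 of 25 cholesterol synthesis genes rose, while 12 of 21 homing and adhesion and 7 of 19 cytokine feedback genes fell. Each of these lists had camera adjusted p = 0.0346 with an estimated correlation. With all libraries, 9 homing and adhesion genes fell and 1 rose.

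In limma 2971 genes passed, 1487 higher and 1484 lower in the organoid. Without the 2 stroma-carrying ATO-DLL4 libraries, a setting chosen after seeing the data, 2156 passed (1037 higher, 1119 lower). With only the 10 libraries of both systems in the fit 1597 passed, and without the filter on low values 1443. Kit, higher in the organoid by 0.69 ± 0.20, did not pass there or without either or both OP9-DLL4 DN1 libraries.

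The sixth comparison set the later against the earlier sampling day within system and stage, 6 libraries each. In limma 0 of 12349 genes passed, with 735 at an unadjusted p under 0.05 and 0 called by edgeR. Il2ra differed by 0.37 ± 0.23 (limma adjusted p = 0.809). T-lineage genes had a median of 0.14 (camera adjusted p = 9.24e-04, and adjusted p = 0.720 with an estimated correlation) and 0 of 34 passing singly. Amino acid response genes had a median of -0.11 (camera adjusted p = 0.00400, and adjusted p = 0.720 with an estimated correlation). With the organoid libraries alone 7 genes passed.

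The seventh comparison tested whether the step from DN1 to DN2a Bcl11b- differed between cultures and thymus. The rise of Il2ra was larger in culture by 2.32 ± 0.58 (limma adjusted p = 0.0450), and that of Gzma by 5.51 ± 0.79 (limma adjusted p = 0.00881). Group means of Il2ra went from 8.82 to 221 RPKM in thymus, from 0.892 to 305 in OP9-DLL4, from 2.86 to 337 in ATO-DLL1 and from 2.49 to 317 in ATO-DLL4. Spi1, a transcription factor of myeloid and early progenitor cells, went the other way, at -1.38 ± 0.17, as did Cdkn1a, a cell cycle inhibitor, at -2.12 ± 0.21. In a contrast added after seeing the data, the step of Spi1 also differed between OP9-DLL4 and the organoids, by -2.08. Its culture mean therefore does not hold alike for each culture. Innate lymphoid and NK genes had 5 of 21 members with a larger rise in culture and 0 with a smaller one (camera adjusted p = 1.18e-05, and adjusted p = 0.613 with an estimated correlation). Their median change was 1.92 within OP9-DLL4, -0.19 within thymus and 0 within each organoid. Of 13 B-cell genes 5 had a more negative change in culture than in thymus (camera adjusted p = 3.14e-05, and adjusted p = 0.132 with an estimated correlation). The median change of that list was -2.70 within OP9-DLL4, 0.18 within thymus, 0.07 within ATO-DLL1 and 0 within ATO-DLL4.

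In limma 1086 genes passed, 280 higher and 806 lower, and after quantile normalization 1213 passed, 545 higher and 668 lower, while 322 did without the filter on low values. The thymic DN2a Bcl11b- group has 1 library, assumed to vary like the others. Without 1 of the thymic DN1 libraries 196 genes passed, without the second OP9-DLL4 DN2a Bcl11b- library 1736, and without any 1 of the 4 ATO-DLL1 libraries of these stages 548, 582, 651 or 583. Il2ra lost its call in 15 of 23 alternatives.

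The single-cell library held cells from the ATO-DLL4 culture sorted as lineage-negative, CD44+ and Kit+, and so was open to both DN1 and DN2a cells. It is 1 library, so intervals are exact binomial 95% intervals that cover counting error only and no test was made. Of 6643 barcodes 6239 cells were kept, with a median of 9024 UMIs and 2497 genes. Most cells carried the transcript of CD25: an Il2ra UMI was seen in 86.6% of cells (85.7 to 87.4), against 13.3% (3.76 to 30.7) of 30 myeloid-like cells, whose median depth was 11617.5 UMIs. A Bcl11b UMI was seen in 21.3% (20.3 to 22.3), against 3.33% (0.08 to 17.2) of the myeloid-like cells. Flt3, high in DN1 cells in bulk, was seen in 1.22% of cells. After thinning each cell to 5000 UMIs, which left out 283 cells, Il2ra was seen in 80.3% and Bcl11b in 16.5%.

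Clustering gave 15 clusters. A pair of them, 404 cells or 6.48% (5.88 to 7.11), were Bcl11b-stage T-like, led by Cd3d, Cd3g and Ptcra, the last being part of the pre-T-cell receptor. A cluster of 30 cells, 0.48% (0.32 to 0.69), was myeloid-like, led by Elane, Ms4a3 and Prtn3. The other 12 clusters, 5805 cells or 93.0%, met no fixed name. Among them, cluster 3 (687 cells) was led by Timp2, Fam169b, Il2ra and Fgf3. Clusters 6 and 12 (396 and 209 cells) had Cd3g, Cd3e and Gzma among their 10 leading genes, and cluster 14 (84 cells) was led by Gata2, Myct1 and Apoe. The share of T-like cells was 15.6% at a clustering resolution of 0.5 and 7.61% at 1.5.

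Among thinned cells with an Il2ra UMI, 958 also had a Bcl11b UMI and 3826 did not. Cd3g was seen in 72.1% (69.2 to 75.0) of the former and 9.57% (8.65 to 10.5) of the latter, and Thy1 in 82.5% and 25.6%. Spi1 was seen in 14.3% (12.1 to 16.7) and 50.9% (49.3 to 52.5), Lmo2 in 5.11% and 23.1%, and Cd34 in 4.49% and 26.3%. Tcf7 was seen in 71.7% and 64.4%, and Gata3, a regulator of T-cell fate, in 26.5% and 28.7%. Of 1073 genes called in bulk between reporter-positive and reporter-negative DN2a cells, 94.6% (93.1 to 95.9) went the same way here. This description was added after the data were seen. The median was 48.6% over 100 random sets of cells, which ran from 39.9% to 59.7%. For the step from DN1 to DN2a Bcl11b-, 80.4% (78.4 to 82.2) of 1732 genes went the same way between cells with and without an Il2ra UMI. For this step random sets of cells gave a median of 49.2% over 100 draws, which ran from 43.1% to 54.5%. Both intervals take genes as independent, while the random sets spread wider, so the intervals overstate the precision.

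**Figure D5:**
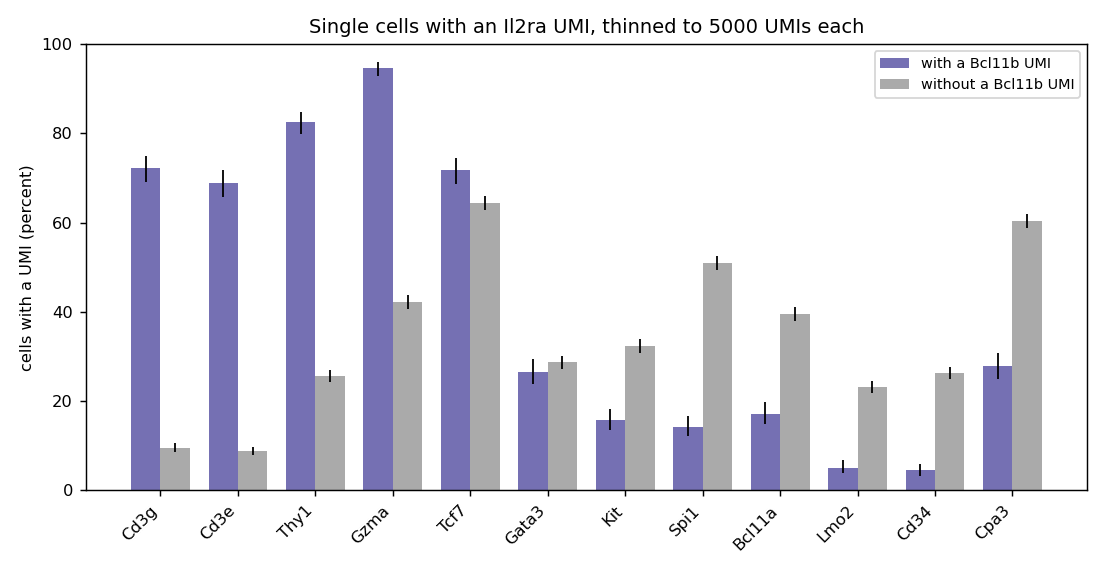
Percent of cells with a UMI of each of 12 genes among single cells with an Il2ra UMI, split by a Bcl11b UMI (958 with, 3826 without), each cell thinned to 5000 UMIs; bars show exact binomial 95% intervals. Cd3g was seen in 72.1% and 9.57%, and Spi1 in 14.3% and 50.9%.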

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

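All 9 tests of explanations below were chosen after the results they bear on were seen, while the exchanges of labels were chosen before. In 44 tests of the libraries of a system on a measure, 4 found a library far from the rest. Chance gives about 1 in 20 for libraries alike in stage, which these were not.

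A pair of ATO-DLL4 libraries carried transcripts of stroma and of Notch ligands. The first DN1 library had 28.39 RPKM of Dll1 and 50.92 RPKM of Dll4, and the second DN2a Bcl11b- library had 15.74 and 0.134 RPKM, while the 8 other organoid libraries had at most 0.394 and 0.442 RPKM. RNA of ligand-bearing stroma cannot be told apart from other sources, because the count of stromal genes above all 8 other organoid libraries, 19 of 21 in the first and 16 in the second, restates the pattern. A single stroma with both ligands is argued against, because the ratio of Dll1 to Dll4 reads differed 211 times between the libraries. Stroma of the DLL1 organoid in the DN2a library cannot be told apart either, because the share that prompted it, 99.2% Dll1 among ligand reads, does not test it, and no biological explanation was tested.

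The OP9-DLL4 DN1 libraries stood apart from the organoid DN1 libraries, with 4523 genes passing in limma (2 against 4 libraries). All 13 measured B-cell genes were higher in OP9-DLL4 (median 2.48, camera adjusted p = 8.20e-13, and adjusted p = 0.00902 with an estimated correlation). This may reflect cells of other lineages within the gate, although the sort was lineage-negative, CD44+ and Kit+ and the cultures began with lineage-depleted marrow. Of the gate genes, Kit was lower in OP9-DLL4 DN1, at -1.41 ± 0.09 (limma adjusted p = 1.11e-06), with 15.5 against 42.9 RPKM. Cd44 was higher, at 0.66 ± 0.11 (limma adjusted p = 8.29e-04). Progenitor regulators were lower for 15 of 24 and higher for 3 (camera adjusted p = 3.65e-05, and adjusted p = 0.0581 with an estimated correlation). Of 15 Notch targets 9 were lower, which a weaker Notch response, the biological explanation, would also give (adjusted p = 0.238 with an estimated correlation). Dilution of blood-cell RNA by stroma cannot be decided from the myeloid genes, which were higher, with a median of 1.15. Cells of other lineages would raise them with or without dilution. Ptprc, a gene shared by blood cells, differed by -0.06 ± 0.12 (limma adjusted p = 0.716), but 1 gene does not settle it. An exchange of column names with the 5 columns that match no sample cannot be told apart from these, since those columns have no labels here.

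In the second OP9-DLL4 DN2a Bcl11b- library Y-linked genes had a mean log2 level of 1.40, against 0.0241 to 0.181 in the other 4 OP9-DLL4 libraries, so that it lay far from them. Eif2s3y was at 4.939 RPKM and Ddx3y at 2.169 RPKM, against at most 0.296 and 0.17 RPKM. A Y-bearing OP9 stroma is argued against, because Eif2s3y per Col1a1 was 57.6 times the median of the other 4. Replacement of most cells by male cells is argued against too, as Xist stood at 106.1% of the mean of the others. A minor share of male cells could remain, and no biological explanation was tested.

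Other libraries far from the rest of their system, in which stages are mixed, are given as values. In the first ATO-DLL4 DN1 library Y-linked genes had a mean log2 level of 0.206, against 0.0183 to 0.0454 in the other 4 ATO-DLL4 libraries. The 10 most abundant genes held 5.14% of reads in the first ATO-DLL1 DN1 library, against 4.71 to 4.81% in the other 4. Immediate early and stress genes had a mean log2 level of 2.29 in the ATO-DLL1 DN2a Bcl11b+ library, against 2.45 to 2.51. That library is the only one of its stage in ATO-DLL1, so stage and an outlying library cannot be told apart.

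The step from DN1 to DN2a Bcl11b- differed between cultures and thymus at 1086 genes by a test of the difference. These included Il2ra at 2.32, Gzma at 5.51, Cdkn1a at -2.12, Cebpb at -2.03 and Spi1 at -1.38. That count was 196 without 1 of the thymic DN1 libraries and 322 without the filter on low values. Il2ra lost its call in most alternatives. A test added after the data were seen found 2206 genes for which the same step differed between OP9-DLL4 and the organoids, 1222 without the first OP9-DLL4 DN1 library and 909 without the filter on low values. Among them were Kit at 1.39, the adaptor Lat at 3.06, Hes1 at 1.68, Nrarp at 1.498, Spi1 at -2.08 and Irf8, a transcription factor of myeloid and B cells, at -3.09, although Nrarp (1.546 and 1.449) did not pass without the first or the second OP9-DLL4 DN1 library, nor Irf8 (-2.59) without the second. Thinned to equal depth, the OP9-DLL4 DN2a Bcl11b- libraries had 392 and 749 genes with 1 to 3 reads and the OP9-DLL4 DN1 libraries 1878 and 1963. Of 13 B-cell genes 12 had a more negative change in OP9-DLL4, where the median change of the list was -2.70, than in the organoids (camera adjusted p = 9.70e-15, and adjusted p = 0.00584 with an estimated correlation).

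With labels exchanged within system or stage, the true labels alone reached their count of calls, 1 of 100 splits for DN2a Bcl11b- against DN1 (highest other 142) and 1 of 54 for the reporter (36). The same held in 1 of 100 for cultures against thymus (3663), and in 1 of 36 each for OP9-DLL4 (5696), ATO-DLL1 (2341) and ATO-DLL4 (3910) against thymus and for ATO-DLL4 against OP9-DLL4 (700). For ATO-DLL4 against ATO-DLL1, 2 of 36 splits reached the count of 1. For the day 32 of 32 reached 0, which every split must, so that exchange tests nothing.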

How the results depend on the processing

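Over all alternatives, 16510 of 17760 results for genes and lists kept their direction and side of the threshold, 1214 kept the direction and lost the call, and 36 turned. With 1 library left out in turn 11883 of 12529 were kept, and under the other settings 4627 of 5231. Without a filter on low values 534 of 664 were kept. Smaller shares were kept within 1 system and with the block, and 10 of 119 turned within thymus. All named genes that passed in the main fit were included, and the lists were those with a camera call there. Among counts and shares 253 stayed and 49 moved. Causes were not tested. Contrasts within 1 system compare fewer libraries, in a fit that still holds all 19, and fits without the filter test more genes. Leaving out the doublets was not run, because Scrublet marked so few cells. A comparison of progenitor and T classes only was not run either, because 2 of 379 cells lacked an Il2ra UMI. Low depth limits genes under about 3 reads.

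For DN2a Bcl11b- against DN1, with 1873 genes, the count was 1012 without a filter, 2999 with a mean per group, 3418 within OP9-DLL4, 627 within ATO-DLL1 and 1001 within ATO-DLL4. For the reporter, with 1130, it was 430 without a filter, 2314 with a mean per group, 153 within thymus, 535 within ATO-DLL1 and 695 within ATO-DLL4. In each of these contrasts within 1 system, 1 Bcl11b+ library stands alone in its arm, and in thymus it faces 1 library. Such an arm has no spread of its own. The reporter counts within 1 system therefore rest on spread from all 19 libraries and are not read as calls. For ATO-DLL4 against ATO-DLL1, with 1, the count was 4 with a pseudocount of 0.1, 0 without a filter and 2 after quantile normalization. It was 10 with a mean per group, 69 with only the 2 systems and 0 without the stroma-carrying libraries. For ATO-DLL4 against OP9-DLL4, with 2971, it was 1443 without a filter and 1597 with only the 2 systems. The organoids alone gave 7 for the day against 0. Without a filter the difference of stage effects fell to 322 from 1086 for cultures and thymus, and to 909 from 2206 for OP9-DLL4 and organoids. List calls went from 86 to 13 with an estimated correlation.

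Replicate numbers share only a day label: late minus early deviations correlated between stages at 0.30 in OP9-DLL4, 0.20 in ATO-DLL1 and -0.33 in ATO-DLL4. A replicate block for system and day gave 1515 genes for DN2a Bcl11b- against DN1 and 123 for the reporter, where Il2ra stood at -0.209.

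With each library left out in turn, counts ran from 1524 to 2049 for DN2a Bcl11b- against DN1, 662 to 1290 for the reporter, 5741 to 7089 for cultures, 6003 to 7042 for OP9-DLL4, 4286 to 5650 for ATO-DLL1, 4951 to 6173 for ATO-DLL4, 0 to 4 for ATO-DLL4 against ATO-DLL1, 2207 to 3357 for ATO-DLL4 against OP9-DLL4, 0 to 0 for the day, 196 to 1736 for the stage effect of cultures and thymus and 1222 to 2674 for that of OP9-DLL4 and organoids.

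Values that turned in DN2a Bcl11b- against DN1 were, within thymus, Rag1 -0.002, Gadd45b 0.086, Socs3 0.576, B-cell genes 0.18, innate lymphoid and NK genes -0.19 and DN3 genes -0.01. Within OP9-DLL4 they were Il1rl1 0.011 and Slfn8 0.05. B-cell genes stood at 0.07 within ATO-DLL1, 0 within ATO-DLL4 and 0.04 without OP9-DLL4, where innate genes stood at -0.13; without both OP9-DLL4 DN1 libraries they stood at 0.05 and -0.18. For the reporter they were, within thymus, Klf4 -0.077, Ndrg1 -0.075, Nop56 0.027 and interferon genes -0.02; within OP9-DLL4, cholesterol genes 0.02 and ribosomal genes 0.12; and interferon genes -0.03 without the OP9-DLL4 Bcl11b+ library (up to 0.51 without others). For ATO-DLL4 against ATO-DLL1, Il2ra stood at 0.185 without the stroma-carrying libraries and 0.107 without the first ATO-DLL4 DN1 library (down to -0.321 without others). Kit stood at 0.003 without the stroma-carrying libraries, 0.005 in edgeR, and -0.109 to 0.047 with 1 library left out (above 0 also at 0.004, 0.008, 0.028 and 0.042). In edgeR the stage effects of Bcl11b were 2.449 and -1.232, of Cd14 1.5 and of Ctsh 0.34. Innate genes stood at -0.03 for the day in the organoids alone.

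In single cells, thinning gave 80.32% for Il2ra and 16.49% for Bcl11b. T-like cells were 15.61% at resolution 0.5, 7.61% at 1.5 and 9.45% with all barcodes. Without thinning 84.65% of genes went the same way.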

Other observations

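The genes here were picked after their values were seen and stand for no tested list. The fixed innate lymphoid and NK list had adjusted p = 0.7103 for OP9-DLL4 against thymus and 0.398 for ATO-DLL4 against OP9-DLL4 with an estimated correlation. In OP9-DLL4 DN2a libraries Cd8a, a co-receptor chain of later T cells, was at 0.912 and 15.74 RPKM in the first and second Bcl11b- libraries and 37.64 RPKM in the Bcl11b+ library, against at most 0.054 RPKM in thymus and 0.159 RPKM in the organoids. In the same order Cd8b1 was at 0.967, 13.1 and 36.49 RPKM, Il2rb at 6.926, 46.85 and 69.66 RPKM, and Ms4a4b, a membrane protein of T cells, at 5.521, 50.83 and 77.28 RPKM. Xcl1, a chemokine of NK and CD8 T cells, was at 2.776, 27.64 and 41.33 RPKM and was listed at 0 in the organoids. Tbx21, a transcription factor of cytotoxic cells, was at 0.177, 3.73 and 5.566 RPKM. Dntt was at 302.8 RPKM in the OP9-DLL4 Bcl11b+ library and at most 16.39 RPKM in the other OP9-DLL4 libraries, between 174.2 and 493.9 RPKM in thymus and at most 2.485 RPKM in the organoids. These OP9-DLL4 columns were matched by name. The first Bcl11b- library was of day 4, and the second Bcl11b- and the Bcl11b+ library were of day 6. The second Bcl11b- library is also the one with Y-linked transcripts, described above. The higher levels in the later libraries therefore cannot be set apart from the day or from that library.

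The Bcl11b+ libraries differed in some genes that rose with the reporter. H19 was at 7.548 RPKM in thymus, 13.59 in OP9-DLL4, 53.08 in ATO-DLL1 and 67.64 in ATO-DLL4. Ctla4 was at 0.12, 44.96, 35.4 and 22.06 RPKM in the same order, and Gzma at 14.09, 782, 428.8 and 921.3 RPKM.

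Thinned to 9.8 M gene reads (M for mega), the number of genes seen with 1 to 3 reads was 392 and 749 in the OP9-DLL4 DN2a Bcl11b- libraries and 620 to 973 in ATO-DLL4. It was 1382 to 1752 in thymus, 1448 to 1696 in ATO-DLL1 and 1706 to 1963 in the other OP9-DLL4 libraries.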
